A study of Homo sapiens with 11 samples.

How the data were processed

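RNA of dermal fibroblasts from human skin was measured on 11 Affymetrix exon arrays. Per the labels, the cells were expanded from punch biopsies of the sole, the palm, the back of the foot and the back of the hand, taken from distinct donors. The labels' growth protocol instead describes an epidermal sample that was not grown, so the labels disagree on the material. Per the labels' protocols, RNA was amplified with random primers and labelled with biotin. Sample titles and source, which name dermal fibroblasts, were followed. Groups were taken from the sample titles, which gave 3 arrays for sole, 2 for palm, 3 for foot back and 3 for hand back. A palm array is recorded as failed in the series' design text. Arrays labelled volar are those of sole and palm, and arrays labelled lower extremity are those of sole and foot back. The labels do not say which arrays came from which of the distinct donors, so it is open whether any arrays share a donor.

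The deposited values are log2 signals per probe set, from 1.93 to 14.37 in all columns. Per the submitters' processing notes, Affymetrix Expression Console and PLIER, a probe-level summary method, were used, and hg19 was named as the genome build. Their versions, the background correction and the order of steps are not given in the sources used here. The array medians lay between 6.48 and 6.53. The columns were not quantile normalized to identical distributions, since the highest and the lowest array differed by a median of 0.105 log2 units at the same rank. The log2 scale was read from the values. The values were used as deposited, with no further normalization and no filter on dim probe sets. The number of arrays limits the precision.

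Of the 28073 probe sets, 21623 carried 1 gene symbol in the platform annotation, 4333 carried several and 2117 were unnamed there. Symbols were checked by gene identifier against NCBI's table for GRCh38.p14, where 21548 were found and 0 changed. No coordinates are given, because that build is not the one named for the arrays. Y-linked and X-inactivation probe sets, and unnamed probe sets numbered among the Y-linked ones, 143 in all, were left out of every test. This left 27930 probe sets. Genes were represented by the probe set with the highest mean over all arrays among those with exactly 1 symbol, which gave 17467 genes, 2603 of them with several probe sets.

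Each comparison used limma 3.58.1 in R 4.3.3, with a mean for each of the 4 sites over all 11 arrays, empirical Bayes variances with an intensity trend, two-sided contrasts and Benjamini-Hochberg adjustment over all probe sets at a threshold of 0.05. The fit had 7 residual degrees of freedom and a prior of 3.5. Values are log2 differences with the standard error (SE) of this fit. The difference between arrays labelled volar and non-volar was averaged over the 2 extremities, so the missing palm array does not weight it. The 33 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Of 770 listed genes, 658 were matched. The p-values rest on the spread between arrays of the same labelled site.

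The test, the lists and the rule for named genes were fixed before the data were examined. That rule takes, for the comparisons of volar with non-volar skin and of lower with upper extremity, the 10 largest differences in each direction among genes past the threshold, and for the others the 5 largest. Where fewer than 5 pass in a direction, those with the smallest p fill up to 5, given as values. For each list up to 4 members that pass are named, or up to 2 with the smallest p; their values are given for lists that camera called and, between volar and non-volar skin, for all lists. Further, 15 genes are named whatever their values, of which HOXA13 and KRT5 had no probe set with exactly 1 symbol and are not reported. Members that pass when adjusted over the list alone are named as well, and were chosen after their values were seen.

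The scripts were tested on simulated arrays with the real means and spreads, where 100 of 27930 probe sets were changed 2-fold and 100 changed 4-fold. At a 2-fold change limma recovered 94% for volar against non-volar skin, 73% for sole against foot back, 74% for palm against hand back, 96% for lower against upper extremity and 38% for the interaction. At a 4-fold change it recovered 100%, 99%, 99%, 100% and 92% in the same order. Among unchanged probe sets it called 11, 13, 9, 6 and 15. In a simulation of the volar comparison over 17467 genes, camera called 5 of 5 shifted lists and 0 of 28 unchanged ones. Simulated genes were independent, so this says nothing about lists whose members are correlated. Simulated noise was normal around 1 mean per site, so the recovered shares do not cover arrays that lie apart from their labelled site. In the real arrays 26 probe sets differed over 2-fold between those labelled volar and non-volar, and 0 passed.

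Single limb genes were compared between labelled groups by an exact two-sided permutation test over all 462 splits, adjusted over the 8 genes tested. This test and its set of 8 genes were chosen after the results were seen. Alternatives tried were the replicate number as a fixed or a random block, quantile normalization, centring of each array on its median, leaving out dim probe sets, eBayes without a trend or robust, array weights (their estimation stopped before it converged), fits of only the arrays compared or of an additive model, a threshold of 0.10, and leaving out each array. An alternative offset before taking logs did not apply, because the values were already on a log2 scale. Leaving out palm replicate 1 and hand back replicate 2 together was added after seeing the data. Figures were drawn with matplotlib 3.10.9.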

Results

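The series title names a comparison of volar skin, the skin of palms and soles, with non-volar skin of the hands and feet. Expression was measured in cultured dermal fibroblasts on 3 arrays labelled sole, 2 labelled palm, 3 labelled foot back and 3 labelled hand back. That makes 5 arrays labelled volar and 6 labelled non-volar, or 6 labelled lower and 5 labelled upper extremity. The median pairwise correlation across probe sets was 0.98 for arrays of 1 labelled site and 0.979 for arrays of different sites. The first principal component held 31.2% of the variance, with palm replicate 1 at 45.3 and hand back replicate 2 at -49.4 as its ends. COL1A1, a collagen chain known from fibroblasts, had a mean log2 signal of 10.33 ± 0.13 (SD, n = 5) in arrays labelled volar and 10.21 ± 0.15 (SD, n = 6) in those labelled non-volar. For VIM, the mesenchymal intermediate filament vimentin, the means were 11.18 ± 0.25 and 10.97 ± 0.22. Of the epidermal keratins, KRT9 lay between 5.44 and 6.19 and KRT14 between 5.48 and 7.19, the latter on palm replicate 1. The array medians were 6.48 to 6.53.

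Genes of limb identity ran against the extremity labels. HOXC10, known from hindlimb development, had a mean log2 signal of 6.74 ± 1.30 (SD, n = 6) in the arrays labelled lower extremity and 8.73 ± 0.47 (SD, n = 5) in those labelled upper. PITX1 and TBX4, both hindlimb factors, were at 7.73 ± 0.55 and 7.33 ± 0.65 in the arrays labelled lower against 8.52 ± 0.21 and 8.51 ± 0.54 in those labelled upper. TBX5, the forelimb factor, went the other way, with 8.32 ± 0.42 in the arrays labelled lower and 7.42 ± 0.29 in those labelled upper. By exact permutation tests, two-sided, p was 0.0173 for HOXC10, 0.0238 for PITX1, 0.0195 for TBX4 and 0.0108 for TBX5. Their Benjamini-Hochberg adjusted p over the 8 genes tested was 0.0297 for each, also by the exact test. The set of 8 was chosen after the results were seen and leaves out HOXD13, so the adjustment does not cover that choice. The posterior HOXC genes HOXC9 and HOXC11, added after their values were seen, differed by -1.13 and -1.36, with exact permutation p of 0.0238 and 0.026. HOXC10 left its widest gap between 6.61 and 8.21, and 10 of the 11 arrays, 5 of 6 labelled lower and 5 of 5 labelled upper, lay on the side opposite to the one known for their labelled limb. All directions given here therefore follow the labels and hold for the arrays labelled so, not for sites known to be right.

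**Figure D1:**
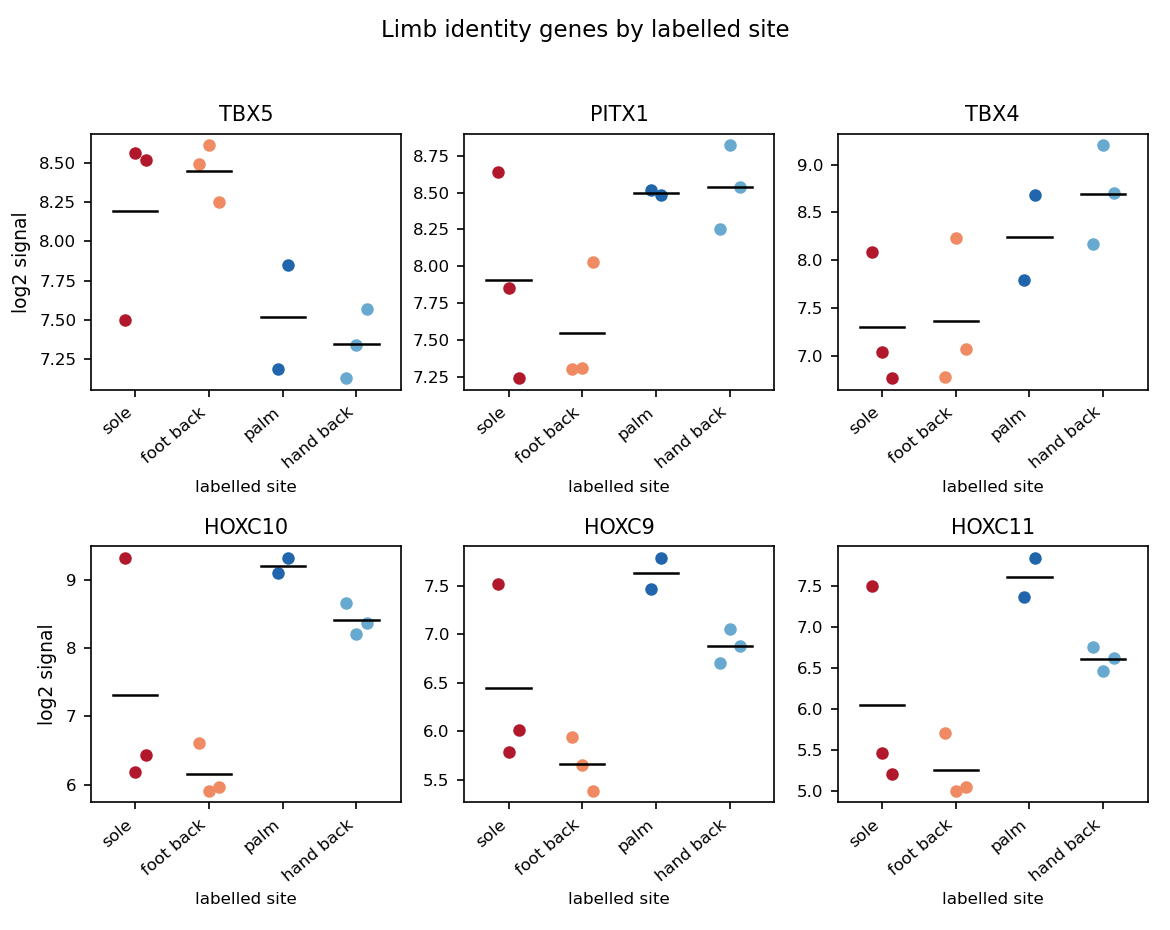
Log2 signal (vertical axes) of TBX5, PITX1, TBX4, HOXC10, HOXC9 and HOXC11 on each array, grouped by labelled site; each point is 1 array and each line the mean of its 2 or 3 arrays. HOXC10 lies between 5.91 and 6.61 on 5 of the 6 arrays labelled sole or foot back and at 8.21 or more on the 5 labelled palm or hand back, and TBX5 is lower in the latter.

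Across all genes, the smallest p between the arrays labelled lower and upper extremity belonged to SIM1, a transcription factor of the bHLH-PAS family, at -1.62 ± 0.21 (SE, n = 6 and 5), which did not pass (adjusted p = 0.326). Other values below 0 were -1.21 ± 0.28 for HOXC9, -0.94 ± 0.21 for LAPTM5, a lysosomal protein of blood cells, -0.51 ± 0.11 for SYP, the synaptic vesicle protein synaptophysin, and -0.45 ± 0.09 for NRP2, a semaphorin and VEGF receptor. On the other side lay TBX5-AS1, the antisense neighbour of TBX5, at 1.48 ± 0.33, TBX5 at 0.89 ± 0.21, CCDC150 at 0.81 ± 0.15, RPL36AP40 at 0.38 ± 0.09 and TMEM47 at 0.35 ± 0.08. In the same fit HOXC10 was at -2.08 ± 0.49, TBX4 at -1.13 ± 0.33, PITX1 at -0.79 ± 0.24 and HOXD13, a distal limb gene, at 0.12 ± 0.13, all with an adjusted p of 1. HOXD13 was at 0.04 without foot back replicate 3, 0.05 without palm replicate 3, 0.07 without hand back replicate 3 and 0.19 without palm replicate 1. CCDC150's other probe sets were at 0.00 and -0.07. RPL36AP40 was dim, between 2.77 and 3.53, below the lower quartile of every array (5.21 to 5.39). With limma 0 of 27930 probe sets passed, against 535 at an unadjusted p under 0.05, where evenly spread p-values give 1396. Without sole replicate 1, 7 passed, among them HOXC10 at -2.58 (adjusted p = 7.07e-04, between that and 1 over its 16 alternatives) and SIM1 at -1.80 (adjusted p = 0.00311, between that and 1 over 16).

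Of the 33 lists, camera called 10 between the arrays labelled lower and upper extremity; with an estimated correlation it called 0, and fry called 0. The HOXC genes were lower in the arrays labelled lower, with 6 of 6 measured members below 0, a median of -0.99 and an adjusted p of 5.8e-12 (adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, 4 of them passed, HOXC8, HOXC9, HOXC10 and HOXC11, and 0 passed over all genes tested. In the wider HOX list 5 passed when adjusted over the list alone, those 4 and HOXB2 at 0.77 ± 0.23, but the list was not called (adjusted p = 0.65), and its median of 0.05 and its mean and test differed in sign. Also lower were contractile and myofibroblast genes (median -0.12, adjusted p = 0.0078), with TPM1, a tropomyosin, at -0.50 ± 0.18 and SMTN at -0.14 ± 0.08, and inflammatory cytokines and chemokines (median -0.10, adjusted p = 0.0078), with CXCL8 at -0.35 ± 0.12 and IL1B at -0.27 ± 0.11. For both the adjusted p = 0.71 with an estimated correlation. YAP and mechanical response targets (median -0.09, adjusted p = 0.0024), with CCN1 at -0.42 ± 0.18 and FJX1 at -0.24 ± 0.08, and immediate early and dissociation stress genes (median -0.13, adjusted p = 0.0027), with IER3 at -0.32 ± 0.21 and IER2 at -0.20 ± 0.11, were lower too, with adjusted p = 0.67 with an estimated correlation for each. Keratinocyte markers were lower (median -0.11, adjusted p = 0.0027; adjusted p = 0.71 with an estimated correlation), with CDSN at -0.67 ± 0.29 and SFN at -0.42 ± 0.19. The HOXC genes were called in each of 11 refits that left out 1 array. The other 5 lists were not called without palm replicate 1, with adjusted p of 0.062 for YAP targets, 0.062 for contractile genes, 0.15 for stress genes, 0.96 for inflammatory genes and 0.97, in the other direction, for keratinocyte markers. Inflammatory genes were not called without hand back replicate 1 either (0.31), nor contractile genes without hand back replicate 2 (0.063), palm replicate 3 (0.13) or sole replicate 2 (0.16). Without palm replicate 3 the median was -0.15 for inflammatory genes, -0.21 for stress genes and -0.25 for keratinocyte markers, and without hand back replicate 1 it was -0.08 for stress genes and -0.05 for contractile genes. Among lists not called, median, mean and test differed in sign in 3, the HOX, Wnt ligand and reticular lists, and the median of the FGF genes changed sign with scaling.

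Higher in the arrays labelled lower were papillary dermis fibroblast markers, with 14 of 16 members above 0 (median 0.22, adjusted p = 0.0025), NTN1 at 1.17 ± 0.51 and WIF1 at 0.36 ± 0.18. Cholesterol synthesis followed with 14 of 15 members above 0 (median 0.10, adjusted p = 0.0052), with IDI1 at 0.45 ± 0.28 and, against the list, PMVK at -0.13 ± 0.07. For both lists the adjusted p = 0.71 with an estimated correlation. Elastic fibre, proteoglycan and matricellular genes (median 0.04, adjusted p = 0.031) and dermal fibroblast markers (median 0.04, adjusted p = 0.044) were called as well, with FBN1, fibrillin 1, at 0.20 ± 0.08 in both lists, FBN2 at 0.77 ± 0.28 and DCN, decorin, at 0.47 ± 0.30; adjusted p = 0.75 with an estimated correlation. LAPTM5 was the 1 immune marker that passed when adjusted over the list alone. Papillary markers were not called without foot back replicate 1 (adjusted p = 0.14), hand back replicate 2 (0.053) or palm replicate 1 (0.65), and cholesterol synthesis not without foot back replicate 1 (0.089) or palm replicate 1 (0.99, its direction turned). Elastic fibre genes kept their call in 4 of 11 refits that left out 1 array, with 0.44 without sole replicate 3, 0.43 without foot back replicate 1, 0.45 without palm replicate 1 and 0.053 to 0.14 without foot back replicate 2, hand back replicate 2, hand back replicate 3 or palm replicate 3. Dermal fibroblast markers kept theirs in 5 of 11, turned without palm replicate 1 (0.75), and had 0.44 without foot back replicate 1, 0.36 without sole replicate 3 and 0.091 to 0.2 without foot back replicate 2, hand back replicate 1 or hand back replicate 2. Without foot back replicate 3 the medians were 0.34 for papillary markers, 0.19 for cholesterol synthesis, 0.11 for elastic fibre genes and 0.11 for dermal fibroblast markers. Without palm replicate 3 they were 0.36 for papillary markers, 0.24 for cholesterol synthesis and 0.14 for dermal fibroblast markers, and without sole replicate 1 they were 0.10 for elastic fibre genes and 0.09 for dermal fibroblast markers. Cholesterol synthesis had 0.06 without foot back replicate 2. In all, camera called 1 list without palm replicate 1, the HOXC genes, and 6 without foot back replicate 1.

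In the arrays labelled volar, LMX1B, a homeobox gene known for dorsal patterning of the developing limb, had a mean log2 signal of 8.92 ± 0.59 (SD, n = 5), against 7.01 ± 0.84 (SD, n = 6) in those labelled non-volar. The difference was 1.95 ± 0.37 (SE), a 3.87-fold value, and its 2 other probe sets were at 1.78 and 0.97. MEIS2, a cofactor of HOX proteins, was at 0.84 ± 0.19, CLDN11, a claudin of tight junctions, at 0.66 ± 0.14 (other probe set 0.73), LOC644285 at 0.65 ± 0.13 (other probe sets 0.25 and 0.16) and LINC01634 at 0.54 ± 0.11. The genes with the smallest p below 0 were FBN2, fibrillin 2 of elastic microfibrils, at -1.26 ± 0.28, PAX9, a paired box factor, at -1.05 ± 0.23, MITF, known as the melanocyte regulator, at -0.71 ± 0.14, CTSLP2 at -0.45 ± 0.10 and LOC730101 at -0.37 ± 0.08. Each had an adjusted p of 0.879 and did not pass. CTSLP2's other probe sets were at -0.01 and 0.09. LINC01634 was dim, between 3.13 and 4.44, below the lower quartile of every array (5.21 to 5.39). EN1, known for ventral limb patterning, was at 0.42 ± 0.15, WNT5A at -0.60 ± 0.23, DKK1, a Wnt antagonist, at -0.12 ± 0.28, KRT9, the keratin of palm and sole epidermis, at 0.03 ± 0.13, KRT14, a basal keratin, at 0.37 ± 0.22, COL1A1 at 0.13 ± 0.10 and VIM at 0.20 ± 0.14. KRT9 changed sign under a replicate block and without palm replicate 1 or hand back replicate 2, and DKK1 without palm replicate 1. Without palm replicate 1 KRT14 was at 0.05, WNT5A at -0.37, COL1A1 at 0.08 and VIM at 0.35, and without palm replicate 3 KRT14 was at 0.69 and VIM at 0.05. Without hand back replicate 2 KRT14 was at 0.24 and COL1A1 at 0.08, and without hand back replicate 1 VIM was at 0.10.

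With limma 0 of 27930 probe sets passed between the arrays labelled volar and non-volar, against 1115 at an unadjusted p under 0.05. Evenly spread p-values give 1396, while other splits of the arrays gave a median of 913. Of the 1115, 578 were higher and 537 lower in the arrays labelled volar. By the exact permutation test p was 0.00866 for LMX1B and 0.0303 for EN1, and 0.0297 and 0.0303 after adjustment over the 8 genes. The adjustment does not cover the choice of these 8 after the results were seen. LMX1B also ran against its known limb side, since its higher values, above a gap from 6.98 to 8.31, were on all 5 arrays labelled volar and 1 labelled non-volar. The means of EN1, the ventral gene, ran with the labels, at 7.77 ± 0.24 (SD) in the arrays labelled volar and 7.33 ± 0.29 in those labelled non-volar. Its widest gap, from 6.95 to 7.17, left 5 arrays labelled volar and 5 labelled non-volar above it, so EN1 did not sort the arrays by skin. Without foot back replicate 1, 14 probe sets passed, among them PAX9 at -1.28 (adjusted p = 0.00406), MITF at -0.84 (adjusted p = 0.0165) and LMX1B at 2.23 (adjusted p = 0.0452); the highest adjusted p over the alternatives of each was 1.

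**Figure D2:**
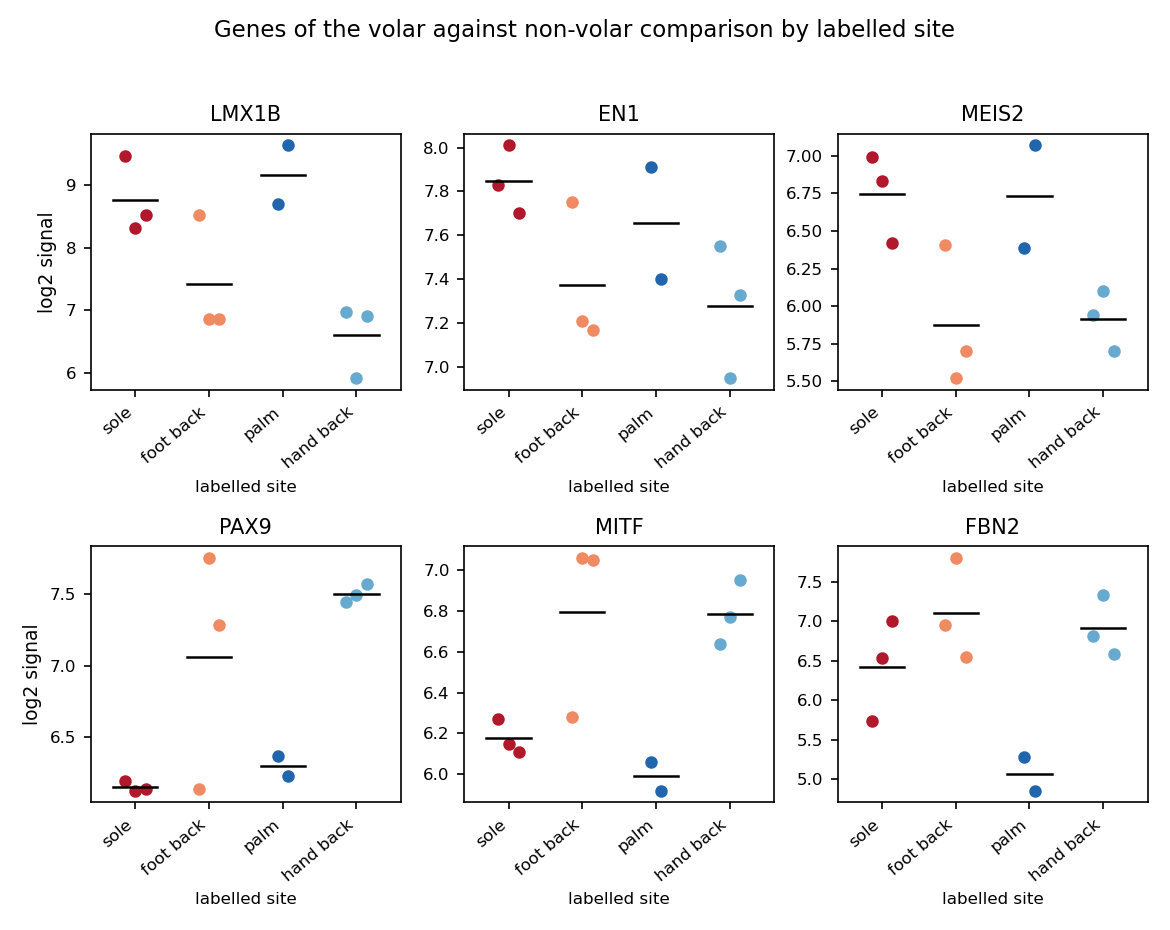
Log2 signal (vertical axes) of LMX1B, EN1, MEIS2, PAX9, MITF and FBN2 on each array, grouped by labelled site; each point is 1 array and each line the mean of its 2 or 3 arrays. LMX1B is higher in the arrays labelled sole and palm by 1.95 on average, and PAX9 lower by a difference of -1.05, while 1 array labelled non-volar lies with the volar ones in both.

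Camera called 4 of the 33 lists between the arrays labelled volar and non-volar; with an estimated correlation it called 0, and fry called 0. HOX genes were higher in the arrays labelled volar, 21 of 22 members being above 0 (median 0.22, adjusted p = 5.8e-08), as were the HOXC genes, 6 of 6 (median 0.76, adjusted p = 1.1e-06). HOXC8 was at 0.76 ± 0.23, HOXD10 at 0.74 ± 0.22, HOXD11 at 0.55 ± 0.15 and HOXC13 at 0.37 ± 0.10, the 4 HOX genes that passed when adjusted over the list alone. Among the HOXC genes 5 passed when adjusted over the list alone, HOXC8, HOXC9, HOXC11, HOXC12 and HOXC13. Immediate early and dissociation stress genes (17 of 19 above 0, median 0.13, adjusted p = 0.02), with EGR3 at 0.58 ± 0.29 and KLF6 at 0.21 ± 0.09, were higher. Cell division genes were lower, 32 of 36 being below 0 (median -0.14, adjusted p = 0.0016), with TTK at -0.40 ± 0.23 and CCNA2 at -0.28 ± 0.18. For each of the 4 lists the adjusted p = 0.78 with an estimated correlation. Hand back replicate 2 exceeded palm replicate 1 in 32 of 36 cell division genes, and with both left out, a setting chosen after seeing the data, the cell division list had an adjusted p of 0.99 and the stress list 0.71, while HOX and HOXC genes had 0.0022 and 3.3e-05. HOX and HOXC genes were also called in each of 11 refits that left out 1 array, but the HOXC median fell from 0.76 to 0.48 without sole replicate 1 and the HOX median from 0.22 to 0.14 without palm replicate 1. Cell division genes were not called without foot back replicate 3 (adjusted p = 0.43) or hand back replicate 2 (0.31). Stress genes were not called without foot back replicate 1 (0.051), hand back replicate 2 (0.1), sole replicate 1 (0.076) or palm replicate 1 (0.12). The cell division median was -0.24 without hand back replicate 1 and -0.09 without palm replicate 1 or sole replicate 3, and without palm replicate 3 the stress median was 0.20. In all, camera called 2 lists without hand back replicate 2, 7 without hand back replicate 1 or sole replicate 2, and 12 without palm replicate 1.

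Limb identity and patterning factors were not called as a list (28 of 41 above 0, adjusted p = 0.16), but 8 passed when adjusted over the list alone and 0 over all genes tested. These were LMX1B, MEIS2, EMX2 at 1.24 ± 0.34 and IRX2 at 0.80 ± 0.21 above 0, and LHX9 at -2.08 ± 0.59, PAX9, LHX2 at -1.04 ± 0.25 and TBX18 at -0.48 ± 0.14 below 0. Adjusted over the list alone, MITF passed among melanocyte markers, FBN2 among elastic fibre genes and FABP4, a lipid chaperone, at -0.38 ± 0.10 among adipocyte markers.

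The other lists were not called by camera between the arrays labelled volar and non-volar, with adjusted p from 0.056 upward. The lowest belonged to keratinocyte markers, with 19 of 20 members above 0 and a median of 0.16. With palm replicate 1 and hand back replicate 2 both left out, chosen after seeing the data, camera called 14 lists, 12 of them from these. Inflammatory cytokines (adjusted p = 7e-05), reticular markers (0.0022), retinoic acid genes (0.0022), adipocyte (0.0066) and sweat gland markers (0.026), BMP and TGF-beta genes (0.026) and keratinocyte markers (0.049), whose median was above 0 over all arrays, were then lower. Papillary markers (0.0022), cholesterol synthesis (0.0022), dermal fibroblast markers (0.0076), collagens (0.048) and FGF genes (0.049) were then higher. In that setting too, with 1 palm array, 0 lists were called with an estimated correlation or by fry; for the 14 lists the adjusted p = 0.51 to 0.57 with an estimated correlation and 0.67 to 0.69 by fry. Over all arrays the median log2 differences were 0.09 for limb factors, 0.09 for Wnt ligands and secreted regulators, 0.09 for canonical Wnt targets, 0.11 for FGF genes and 0.10 for fibrillar and other collagens. Matrix proteases and inhibitors had a median of 0.05, papillary dermis markers 0.12, reticular dermis markers -0.15 and dermal papilla and hair follicle mesenchyme markers 0.05. The median was 0.08 for contractile genes, 0.03 for dermal fibroblast markers, 0.02 for cholesterol synthesis, 0.01 for hypoxia and glycolysis, -0.04 for ribosomal proteins, -0.02 for senescence and p53 targets, -0.06 for inflammatory cytokines and -0.03 for interferon response. Among markers of other cells it was 0.10 for endothelial cells, 0.07 for immune cells, 0.11 for Schwann cells, 0.05 for pericytes and smooth muscle, and 0.08 for sweat glands. In 6 lists median, mean and test differed in sign: elastic fibre genes (median 0.02), retinoic acid genes (0.04), melanocyte (0.06) and adipocyte markers (0.02) and BMP and TGF-beta genes (0.00) had a mean below 0, and YAP targets had a median of -0.01 and a mean of 0.00. The medians of the BMP and TGF-beta genes and of the YAP targets also changed sign with scaling.

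In each of these lists the pair of members with the smallest p between the arrays labelled volar and non-volar had the following values (SE, n = 5 and 6). Beside MITF, FBN2, FABP4 and the limb factors above, 0 of them passed when adjusted over the list alone. WNT2 was at 0.29 ± 0.10 and RSPO4 at -0.33 ± 0.12 among Wnt ligands and secreted regulators. BAMBI was at -0.40 ± 0.15 and SP5 at 0.22 ± 0.09 among canonical Wnt targets. TGFB2 was at -0.55 ± 0.15, beside BAMBI, among BMP and TGF-beta genes. FGF18 was at 0.17 ± 0.07 and FGFR1 at 0.14 ± 0.07. Among matrix genes were COL23A1 at 0.31 ± 0.09 and COL5A1 at 0.21 ± 0.10 for collagens, and FBN2 and SPON2 at 0.23 ± 0.09 for elastic fibre genes. Proteases held ADAMTS5 at -0.57 ± 0.29 and MMP1 at 0.82 ± 0.48. Fibroblast lists held COL23A1 and WIF1 at 0.32 ± 0.18 (papillary), CDH2 at -0.66 ± 0.29 and COL11A1 at -0.52 ± 0.36 (reticular). They also held TBX18 and LEPR at 0.25 ± 0.11 (dermal papilla), and DCN at -0.67 ± 0.30 and COL5A1 (dermal fibroblast markers). For retinoic acid genes RDH10 was at -0.82 ± 0.28 and RARB at -0.70 ± 0.24. For contractile genes PALLD was at 0.20 ± 0.11 and TPM1 at 0.29 ± 0.18, and for YAP targets IGFBP3 at 0.58 ± 0.28, beside TGFB2. ZMAT3 was at -0.35 ± 0.13 and CDKN2A at 0.21 ± 0.09 among senescence and p53 targets. IL1B was at 0.23 ± 0.11 and CSF3 at 0.17 ± 0.10 among inflammatory cytokines, and USP18 at -0.90 ± 0.28 and IFI27 at 0.40 ± 0.13 in the interferon response. HK2 was at 0.44 ± 0.21 and ADM at 0.18 ± 0.13 for hypoxia and glycolysis. MVK was at 0.17 ± 0.08 and IDI1 at -0.34 ± 0.28 for cholesterol synthesis, and RPL7 at -0.22 ± 0.13 and RPL23 at 0.16 ± 0.10 for ribosomal proteins. Among markers of other cells these were PERP at -0.24 ± 0.10 and KRT10 at 0.19 ± 0.09 (keratinocyte), MITF and EDNRB at -0.75 ± 0.30 (melanocyte). Further pairs were FLT1 at -0.66 ± 0.32 and TIE1 at 0.17 ± 0.08 (endothelial), and CD2 at 0.16 ± 0.09 and CSF1R at 0.12 ± 0.08 (immune). The last lists held GFRA3 at 0.32 ± 0.15 and CDH19 at 0.15 ± 0.10 (Schwann), CNN1 at 0.24 ± 0.19 and PLN at 0.10 ± 0.11 (pericyte). Glands and fat held SLC12A2 at -0.26 ± 0.08 and FOXI1 at 0.16 ± 0.08 (sweat gland), and FABP4 and LPL at 0.10 ± 0.09 (adipocyte).

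Between the arrays labelled sole and foot back, 3 of each, the smallest p among named genes above 0 belonged to SLC27A4, a fatty acid transporter, at 0.57 ± 0.12 (SE), LINC01634 at 0.59 ± 0.15, LINC01512 at 0.52 ± 0.13, GUSBP19 at 0.49 ± 0.13 and LINC02809 at 0.48 ± 0.12. Below 0 lay OR52B4, an olfactory receptor gene, at -1.57 ± 0.36, ZNF835 at -1.18 ± 0.29, TOR4A at -0.83 ± 0.24, PLEKHG4B at -0.52 ± 0.15 and TRIM68 at -0.43 ± 0.13. Each had an adjusted p of 1. The other probe set of SLC27A4 was at -0.07, those of GUSBP19 at 0.02 and 0.09, and those of PLEKHG4B at -0.25 and 0.07. ZNF835 (2.67 to 4.27) and LINC01634 (3.13 to 4.44) lay below the lower quartile of every array (5.21 to 5.39). OR52B4 ran from 3.43 to 5.75, around that quartile and below it. With limma 0 of 27930 probe sets passed, against 405 at an unadjusted p under 0.05, where evenly spread p-values give 1396. The smallest adjusted p was 0.158, for a probe set of LINC00674 at -1.14 ± 0.14, while the one used for that gene was at 0.14. Without foot back replicate 1, 4 passed, ZIC1 at 2.85, FOXL2 at 1.16, PAX9 at -1.36 and a probe set without a symbol at 2.49.

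Camera called 4 lists, all higher in the arrays labelled sole; with an estimated correlation it called 0, and fry called 0. The HOX genes had 18 of 22 members above 0 (median 0.17, adjusted p = 3.4e-05) and the HOXC genes 6 of 6 (median 0.72, adjusted p = 5e-06), with HOXC9 at 0.78 ± 0.37 and HOXC8 at 0.66 ± 0.31. Cholesterol synthesis (12 of 15 above 0, median 0.12, adjusted p = 0.02), with MVK at 0.18 ± 0.10 and CYP51A1 at 0.31 ± 0.24, and papillary dermis markers (12 of 16, median 0.11, adjusted p = 0.028), with COL23A1 at 0.24 ± 0.12 and AXIN2 at 0.51 ± 0.31, were the others. For each of the 4 the adjusted p = 0.95 with an estimated correlation. Adjusted over the list alone, 0 members passed in any list, as over all genes. The number of lists called was 2 without hand back replicate 2 or sole replicate 3, 7 without foot back replicate 3, 9 without foot back replicate 1 and 10 without sole replicate 1. HOXC genes were called in each of 11 such refits, but without sole replicate 1 their median was 0.17 instead of 0.72, with an adjusted p that rounds to 0.05, HOXC9 at 0.25, HOXC8 at 0.28, HOXC10 at 0.15 instead of 1.16 and HOXC11 at 0.08 instead of 0.80. HOX genes were called in 10, with a median of 0.29 without foot back replicate 1, and a median of 0.02 and an adjusted p of 0.34 without foot back replicate 2. Without foot back replicate 1 the medians of papillary markers and cholesterol synthesis were 0.32 and 0.22, and without sole replicate 1 that of papillary markers was 0.29. Cholesterol synthesis and papillary markers turned without foot back replicate 3 (0.97 and 0.92) and were not called without hand back replicate 2 (0.053 and 0.053), sole replicate 2 (0.12 and 0.078) or sole replicate 3 (0.06 and 0.63), nor papillary markers without foot back replicate 2 (0.15). Median, mean and test differed in sign in 5 lists not called.

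Between the arrays labelled palm (n = 2) and hand back (n = 3), LMX1B was at 2.56 ± 0.55 (SE), with its other probe sets at 2.33 and 1.28. FPR1, a formyl peptide receptor, was at 0.58 ± 0.14, KCNMB1, a potassium channel subunit of smooth muscle, at 0.56 ± 0.12, MAS1L at 0.56 ± 0.14 and JUP, the junction protein plakoglobin, at 0.55 ± 0.13. Below 0 lay FBN2 at -1.85 ± 0.41, CTSLP2 at -0.73 ± 0.15, LOC730101 at -0.71 ± 0.11, ZNF266 at -0.69 ± 0.15 and DNAH12 at -0.66 ± 0.12. None passed, with an adjusted p of 0.631 for LOC730101 and 0.788 for the others. CTSLP2's other probe sets were at -0.04 and -0.12, and DNAH12's at 0.04, 0.14 and 0.29. MAS1L was dim, between 4.38 and 5.1, below the lower quartile of every array (5.21 to 5.39). With limma 0 of 27930 probe sets passed, against 1508 at an unadjusted p under 0.05, where evenly spread p-values give 1396. Without foot back replicate 1, an array of neither site, 1 probe set without a symbol passed, at 2.40.

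Camera called 7 lists between the arrays labelled palm and hand back; with an estimated correlation it called 0, and fry called 0. Higher in the arrays labelled palm were HOX genes (20 of 22 above 0, median 0.32, adjusted p = 1.3e-05), with HOXD10 at 1.09 ± 0.33 and HOXD11 at 0.84 ± 0.23, HOXC genes (6 of 6, median 0.77, adjusted p = 4.3e-04), with HOXC12 at 0.54 ± 0.17 and HOXC13 at 0.50 ± 0.15, and FGF ligands, receptors and feedback genes (19 of 23, median 0.21, adjusted p = 0.0051), with SPRY4 at 0.46 ± 0.18 and FGF18 at 0.36 ± 0.11. For these 3 and for the immediate early and dissociation stress genes (17 of 19, median 0.24, adjusted p = 0.0046), with EGR3 at 1.22 ± 0.44 and MAFF at 0.32 ± 0.16, the adjusted p = 0.74 with an estimated correlation. Keratinocyte markers were higher (19 of 20, median 0.26, adjusted p = 0.0088), with KRT15 at 0.60 ± 0.33 and, against the list, PERP at -0.26 ± 0.15. Cell division genes (30 of 36 below 0, median -0.24, adjusted p = 8.9e-05), with TTK at -0.80 ± 0.34 and CCNA2 at -0.57 ± 0.27, were lower. Ribosomal proteins were lower too (25 of 30 below 0, median -0.09, adjusted p = 0.0068), with RPL7 at -0.52 ± 0.20 and RPL6 at -0.32 ± 0.14. For these last 3 lists the adjusted p = 0.84 with an estimated correlation. Adjusted over the list alone, 6 members passed: HOXC12 and HOXC13, LMX1B, FBN2, MITF at -0.79 ± 0.22 and FABP4 at -0.61 ± 0.14. HOX genes were called in each of 11 refits that left out 1 array. Without palm replicate 3 the median was 0.49 for HOX genes, 0.43 for stress genes and 0.48 for keratinocyte markers, and without hand back replicate 1 it was -0.50 for cell division genes and -0.16 for ribosomal proteins. HOXC and FGF genes were not called without palm replicate 3 (adjusted p of 0.05, before rounding above the threshold, and 0.27). Without hand back replicate 2 camera called 2 lists, the HOX and HOXC genes, and the others had 0.37 for cell division genes, 0.37 for ribosomal proteins, 0.088 for FGF genes, 0.059 for stress genes and 0.18 for keratinocyte markers. Without palm replicate 1 stress genes had 0.073, ribosomal proteins 0.064 and keratinocyte markers 0.36, in the other direction. Median, mean and test differed in sign in 8 lists not called. With palm replicate 1 and hand back replicate 2 both left out, the cell division, ribosomal and stress lists had adjusted p of 0.98, 0.98 and 0.8, HOX genes 0.13, and keratinocyte markers were called lower instead of higher (adjusted p = 0.012). HOXC (0.0064) and FGF genes (0.012) were still called, and 6 further lists were: papillary markers (0.017) higher, and inflammatory cytokines (2.2e-04), sweat gland (0.0046) and adipocyte markers (0.0046), reticular markers (0.0066) and retinoic acid genes (0.0066) lower. These 9 lists had an adjusted p = 0.60 to 0.74 with an estimated correlation and 0.53 to 0.88 by fry. The median of the ribosomal proteins was -0.05 after quantile normalization.

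The difference between the foot and hand comparisons was tested as an interaction, the difference of sole and foot back minus that of palm and hand back. SIM1 was at 1.79 ± 0.42 (SE), ENPP1, an ectoenzyme that makes pyrophosphate, at 1.07 ± 0.24, SLC27A4 at 0.74 ± 0.18, and LOC730101 and DNAH12 at 0.68 ± 0.15 each. RAB11FIP1 was at -1.42 ± 0.39, NREPP1 at -0.83 ± 0.20, OR52N1 at -0.78 ± 0.22, FPR1 at -0.69 ± 0.19 and ACTL8 at -0.53 ± 0.15, and all 10 had an adjusted p of 1. Other probe sets of SLC27A4, DNAH12 and RAB11FIP1 did not follow, at -0.13, at -0.33 to -0.11, and at -0.12 and 0.11, while that of ENPP1 was at 0.98. NREPP1 (2.83 to 3.66) and OR52N1 (4.12 to 4.88) lay below the lower quartile of every array (5.21 to 5.39). With limma 0 of 27930 probe sets passed, against 698 at an unadjusted p under 0.05, where evenly spread p-values give 1396.

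Camera called 6 lists for the interaction; with an estimated correlation it called 0, and fry called 0. Cell division genes (28 of 36 above 0, median 0.23, adjusted p = 0.001), with TTK at 0.80 ± 0.46 and PCNA at 0.54 ± 0.33, ribosomal proteins (23 of 30, median 0.14, adjusted p = 0.0012), with RPL6 at 0.54 ± 0.19 and, against the list, RPL13 at -0.41 ± 0.18, and cholesterol synthesis (11 of 15, median 0.12, adjusted p = 0.029), with IDI1 at 1.56 ± 0.56 and CYP51A1 at 0.61 ± 0.36, had higher differences in the foot. FGF genes (21 of 23 below 0, median -0.20, adjusted p = 0.0017), with SPRY4 at -0.58 ± 0.24 and FGF18 at -0.39 ± 0.15, immediate early and dissociation stress genes (16 of 19, median -0.22, adjusted p = 0.022), with EGR3 at -1.29 ± 0.59 and MAFF at -0.37 ± 0.22, and keratinocyte markers (18 of 20, median -0.28, adjusted p = 0.029), with IVL at -0.41 ± 0.19 and KRT15 at -0.65 ± 0.44, had lower ones. For each of the 6 the adjusted p = 0.88 with an estimated correlation, and 0 members passed when adjusted over the list alone. Without hand back replicate 2 camera called 0 lists, without sole replicate 2 or sole replicate 3 it called 3, and without sole replicate 1 it called 11. Ribosomal proteins kept their call in 10 of 11 such refits (adjusted p = 0.19 without hand back replicate 2) and FGF genes in 9 (0.19 without hand back replicate 2 and 0.16 without palm replicate 3). Cell division genes kept it in 9, with 0.086 without foot back replicate 1 and 0.61 without hand back replicate 2. Without palm replicate 1 stress genes had 0.27, and cholesterol synthesis (0.9) and keratinocyte markers (0.4) turned; these 3 lists also had 0.24, 0.19 and 0.48 without hand back replicate 2, and 0.082, 0.14 and 0.072 without sole replicate 2. Without sole replicate 3 each had 0.056. Keratinocyte markers had 0.089 and cholesterol synthesis 0.43 without foot back replicate 3. The latter had 0.093 without hand back replicate 1. The median of cell division genes was 0.12 without foot back replicate 2, 0.43 without foot back replicate 3 and 0.45 without hand back replicate 1, that of ribosomal proteins 0.09 without sole replicate 1 and 0.07 after quantile normalization, and that of cholesterol synthesis 0.19 without foot back replicate 1. Without palm replicate 3 it was 0.25 for cholesterol synthesis and -0.41 for stress genes. With palm replicate 1 and hand back replicate 2 both left out, chosen after seeing the data, FGF genes were still called (adjusted p = 0.021) and keratinocyte markers were called in the other direction (0.025), each with adjusted p = 0.96 with an estimated correlation. Cell division genes then had 0.87, ribosomal proteins 0.78, stress genes 0.87 and cholesterol synthesis 0.81. Median, mean and test differed in sign in 2 lists not called.

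Across 27930 probe sets the foot and hand differences had a Pearson r of 0.16 and a Spearman rho of 0.16, and 57.7% had the same sign in both. Probe sets are not independent replicates, so the value was set against 99 regroupings of the arrays within each extremity. These gave r from -0.24 to 0.25, and 6 of them were as large.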

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

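The tests of the limb gene labels, of culture growth and of other splits of the arrays were chosen after the results were seen; those of dim probe sets and of the intensity scale were not. An array far from the rest of its labelled group was found in 10 of 70 groups, where chance gives about 3.5. The gap to the nearest array, as a share of the group's range, was 0.89 for TBX5-AS1, 0.68 for TBX5, 0.705 for HOXC9 and 0.796 for HOXC10. For each of these genes it was the same 1 of the 6 arrays labelled lower extremity, the 1 above HOXC10's widest gap. The share was 0.711 for PAX9 and 0.632 for CTSLP2 among arrays labelled non-volar, 0.795 for KRT14 among those labelled volar and 0.716 for TMEM47 among those labelled upper extremity. For the mean correlation with the other arrays it was 0.846 among arrays labelled volar, where palm replicate 1 had 0.968, and 0.692 among those labelled non-volar, where hand back replicate 2 had 0.968.

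By the camera test of the interaction, foot and hand differences were unequal for 6 lists, with adjusted p of 0.0017 for FGF genes, 0.001 for cell division genes, 0.022 for immediate early and dissociation stress genes, 0.029 for cholesterol synthesis, 0.0012 for ribosomal proteins and 0.029 for keratinocyte markers. With an estimated correlation each had an adjusted p of 0.88.

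Limb identity genes ran against the extremity labels, with 10 of 11 arrays on the unexpected side of HOXC10's widest gap. A single exchanged pair would put at most 2 arrays there, so the 10 argue against it. Upper and lower labels exchanged throughout would put all 11 there. The exception was the same array for HOXC9, HOXC11 and TBX5 as for HOXC10, so it is not a single stray value. It is still 1 array and does not exclude such an exchange, which stays open. An exchange of extremity labels would leave the volar labels in place, so it would not account for the side of LMX1B. When the 6 arrays ranked highest, as many as lie above HOXC10's gap, were set against the rest, HOXC9 and HOXC11 sorted all 11 arrays as HOXC10 did, as did PITX1 and, from the lowest, TBX5, while TBX4 sorted 9 so; by its own widest gap PITX1 has 8 arrays above. Labels attached to other arrays and a limb program that the cultured cells keep apart from their site would both give this. The sorting therefore does not tell them apart. The 6 arrays above HOXC10's gap are as many as those labelled lower extremity. LMX1B's gap also left 6 arrays above it, as many as are labelled non-volar. Labels attached to other arrays would keep such counts, while a kept limb program need not, but equal counts do not exclude that program. The biological explanation is untested, because arrays are not tied to donors.

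Palm replicate 1 and hand back replicate 2, the ends of the first principal component, deviated from the mean of all arrays in opposite directions. Opposite deviations are in part given by that position. Their correlation across probe sets was -0.56, the lowest of all pairs, whose median was -0.10. Noise in dim probe sets would weaken this among bright ones, but over the probe sets above the median mean signal it was -0.60 (95% bootstrap interval over probe sets -0.61 to -0.58). An unequal intensity scale would be removed by quantile normalization, after which it was -0.53. Cell division genes were higher in hand back replicate 2 by a median of 0.65, above all of 10000 random lists matched on mean signal, whose middle 95% ran from -0.16 to 0.23, so unequal growth of the cultures may contribute. Random lists lack the correlation of cell division genes, and the bootstrap interval treats probe sets as independent, so that interval is too narrow. The comparison is between 1 array and 1 array, and no biological explanation was tested.

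Other splits of the arrays decide nothing about chance by the number past the threshold where the labelled one called 0 probe sets. Every split gives at least 0. That holds for volar against non-volar skin (as many in 100 of 100 splits, highest other 8), for lower against upper extremity (100 of 100, highest other 18) and for sole against foot back (10 of 10, highest other 14), where the 10 splits are also too few for a share under 0.05. At an unadjusted p under 0.05, the labelled volar split gave 1115, as many as in 41 of 100 splits, itself included (median of the others 913). Lower against upper extremity gave 535 (87 of 100, median of the others 943). Sole against foot back gave 405 (7 of 10, median of the others 569).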

How the results depend on the processing

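The alternative without both palm replicate 1 and hand back replicate 2 was chosen after seeing the data; the others were planned. In the 5 comparisons 0 probe sets passed under every alternative other than leaving out 1 array, 54 counts in all. That includes a threshold of 0.10, both left-out arrays together, and array weights, whose estimation stopped before it converged. Leaving out 1 array gave 0 in 51 of 55 refits. The counts ranged from 0 to 14 for volar against non-volar skin, from 0 to 4 for sole against foot back and from 0 to 1 for palm against hand back, the higher value each time without foot back replicate 1, and from 0 to 7 for lower against upper extremity, the higher without sole replicate 1. Foot back replicate 1 was the 1 array labelled non-volar above LMX1B's gap, and sole replicate 1 the 1 labelled lower above HOXC10's. Whether they widen the spread within their sites, and so lower the counts over all arrays, was not tested. Where a palm array was left out, the remaining one was assumed to vary like the arrays of the other sites. The alternative offset was not run, since it applies only to linear values.

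As a check of pairing, the deviations of arrays that share a replicate number had correlations from -0.36 to 0.47 in 15 pairs. Of these, 2 were over 0.1, and 3 of 11 arrays correlated best with their own number, so no pairing by number was seen. Deviations were taken from the means of labelled sites, and the numbers from the same titles, so wrong titles could hide a pairing. With the replicate block, fixed or random, 0 probe sets passed in each comparison. With the fixed block the dermal fibroblast list for lower against upper extremity (adjusted p = 0.074) and, for the interaction, cholesterol synthesis (0.11) and keratinocyte markers (0.055) were not called; the other lists called kept their call.

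Lists called by camera fell to 0 in all 5 comparisons with an estimated correlation and with fry. Leaving out 1 array gave 2 to 12 lists for volar against non-volar skin (lowest without hand back replicate 2, highest without palm replicate 1), 2 to 10 for sole against foot back and 0 to 11 for the interaction. The lowest was 2 for palm against hand back, without hand back replicate 2, and 1 for lower against upper extremity, without palm replicate 1. Without palm replicate 1 and hand back replicate 2 together it was 14 for volar against non-volar skin and 3 for lower against upper extremity. The cause was not tested.

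Of 953 values of named genes under alternatives, 941 kept their direction and side of the threshold and 8 passed that had not. KRT9 reversed to -0.02 with the replicate block, to -0.07 without hand back replicate 2 and to -0.03 without palm replicate 1, and DKK1 to 0.07 without palm replicate 1; the cause was not tested. Leaving out 1 array gave -0.07 to 0.11 for KRT9 and -0.34 to 0.07 for DKK1. The correlation of the foot and hand differences stayed between 0.07 and 0.22 in 14 alternatives.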

Other observations

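Some genes outside the rule for named genes passed limma's test when 1 array was left out, and were chosen after their values were seen. Without foot back replicate 1, ZIC1, a zinc finger patterning factor, was at 1.66, EMX2 at 1.57, IRX2 at 1.00, FOXL2 at 0.97 and its neighbour FOXL2NB at 0.93, all higher in the arrays labelled volar. Without sole replicate 1, HOTAIR, a noncoding RNA of the HOXC cluster, was at -1.60 and HOXC11 at -1.82, both lower in the arrays labelled lower extremity, in the direction of HOXC9 and HOXC10 and against the extremity labels as HOXC10 is.

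The arrays most alike did not share a labelled site: the highest correlations across probe sets, 0.991 and 0.990, were between arrays of different sites.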
